A study of Mus musculus with 22 samples.

How the data were processed

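Heart RNA of 22 female C57BL/6 mice was measured on Agilent 2-colour whole-genome arrays, 1 mouse per array and up to 4 arrays on each of 9 slides, scanned on 3 days. The mice had received 162 µg of nano-TiO2 or vehicle into the trachea, in 4 groups: control day 1 (5 mice), nano-TiO2 day 1 (5), control day 28 (6) and nano-TiO2 day 28 (6). Per the labels, heart RNA was labelled with Cy5 and Universal Mouse Reference RNA with Cy3 on every array, with no dye swap, and RNA integrity numbers were 7 and above. The extraction text of the labels speaks of lung, while the tissue label and the text on tissue collection speak of heart.

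The deposited scanner files hold a median intensity of each spot and of its local background in both channels, neither subtracted nor normalized. They also hold a log10 ratio of Cy5 to Cy3 that per the file headers was made by Agilent Feature Extraction 10.7.3.1 with background subtraction and dye normalization. The processing notes of the authors name version 9.5.3.1. The deposited series matrix of the authors holds 1 value per probe on a log2 scale, whose method the labels do not state. Its values correlated at r between 0.992 and 0.998 with log2 ratios made from the same arrays with loess but without background subtraction. Slopes ran from 0.984 to 0.996. The background-corrected ratios used below were not compared with it in this way.

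Log2 ratios were computed from the median intensities, since the files hold no mean intensities, although mean intensities had been planned. R 4.3.3 and limma 3.58.1 were used, with the data.table package (version 1.17.8) for reading and Python 3.11.15 with matplotlib 3.10.9 for figures. Background was corrected with normexp (offset 50) and each array was normalized with loess, control spots at weight 0. Spots marked by the scanner software as uneven or as outliers (0.306%) were left out. The normexp parameters were fitted without the spots marked for an uneven background. On 3 arrays a fit on all spots gave a background SD of 132, 97.1 and 850 against 1.17 to 2.15 on the others, with subtracted Cy5 intensities as low as -70310.5. This choice was made after results with all spots had been seen, and the fit on all spots is given as an alternative. Spots of 1 probe were averaged. Probes well above background in Cy5 on at least 5 of 22 arrays were kept (19273 probes). Probes were matched to symbols through RefSeq accessions, 23374 of them to 16535 genes. A gene was represented by its kept probe with the highest mean Cy5 signal, which gave 15502 genes for testing, 10476 of them with a symbol.

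Between 32.7% and 52.8% of probes per array were well above background in Cy5, and no spot was saturated. Pairs of arrays correlated at r between 0.895 and 0.986. For arrays, their number limits the precision.

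Genes were compared with limma, with a mean for each of the 4 groups and eBayes, and p was adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The contrasts were nano-TiO2 against control at day 1 and at day 28, the difference between these, and day 28 against day 1 controls. For each contrast 27 gene lists were tested, which cover complement, acute phase, cytokines and chemokines, other processes of heart and stress, and markers of 13 cell types or neighbouring tissues. They were tested with camera at a preset correlation of 0.01, with a correlation estimated per list, and with fry, which asks whether the genes of a list move on balance one way or, in its mixed form, in either direction. Exact two-sided permutation tests compared the list means per mouse. Where a gene was not well above background on any array of a group, its fold difference is given as a bound or left out, and its values under alternatives lie near background. The design, the lists, the tests and the alternatives were set before the data were examined, except where the text says that a choice came later. The lists of liver, smooth muscle, ventricular and further atrial genes were added later.

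Named genes followed a fixed rule. For day 1 and day 28 they were the 12 largest rises and falls past the threshold, or up to 5 genes with the smallest p in each direction where fewer than 5 passed. Added to these were the 6 complement members with the smallest p, and 3 members of each other list that passed and of the acute phase and cytokine lists. For the other contrasts they were the 5 genes with the smallest p in each direction. Clone names and predicted genes were passed over, 1 of them recognised as a clone name only after the results were seen, with Mterf1b in its place, and 6 heart and lung genes were named to check the tissue. Of the day 28 genes picked by this rule, 1 is not reported here.

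Alternatives were plain or no background subtraction, the scanner log ratios, the series matrix, median centring, scaling between arrays, Cy5 alone, other filters and probe summaries, trend and robust eBayes, array weights, only the compared groups, slide or scan day as a block, other thresholds and set tests, and leaving out each array. Added after the data were seen were the normexp fit on all spots, leaving out arrays with almost no atrial transcripts or with lung epithelium or liver transcripts, adipocyte and atrial scores as covariates, the complement list without Cfd, and exact permutation. The tests were tried on simulated data with independent noise, where 67.7% to 75.4% of genes changed by 0.5 in log2 and at least 98.3% of those changed by 1 or 2 were called, and 3.19% to 3.80% of calls were false. Real lists have correlated members, which the simulation did not hold.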

Results

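Gene expression was measured in the hearts of 22 female C57BL/6 mice on Agilent 2-colour arrays, 1 mouse per array. The mice had received a single instillation into the trachea of 162 µg of nanosized titanium dioxide (nano-TiO2) or of the vehicle alone, and their hearts were taken 1 or 28 days later. The groups held 5 control and 5 nano-TiO2 mice at day 1, and 6 control and 6 nano-TiO2 mice at day 28. Heart RNA was labelled with Cy5 and compared on every array with a common reference RNA in Cy3, so each value is a log2 ratio of heart to reference. Between 13473 and 21751 probes per array (32.7% to 52.8%) were well above background in the Cy5 channel. The number of arrays per group limits the precision of every value below.

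The tissue label reads heart while the extraction text speaks of lung, so genes of both organs were looked at first. Myh6, the main myosin heavy chain of the adult mouse heart, lay 4.95 ± 0.25 (SD, n = 19 arrays with a value) above the reference in log2. Tnnt2 (cardiac troponin T) lay 5.66 ± 0.22 (SD, n = 21) above it and Actc1 (cardiac actin) 5.96 ± 0.36 (SD, n = 22), each well above background on all 22 arrays. The lung surfactant genes Sftpc and Sftpb were well above background on 0 of 22 arrays. Scgb1a1, the secretory protein of club cells in the airways, was well above background on 6 of 22 arrays, 4 of them day 28 controls, with a highest value of 3.95.

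The first comparison asked which heart genes differed from control 1 day after instillation. No gene passed: limma called 0 of 15502 genes, and 1339 had an unadjusted p under 0.05, of which 931 were higher with nano-TiO2 and 408 lower. The named genes with the smallest p on the higher side were Enc1, Lmod1, Cebpd, Gpx3 and Clu. Enc1, which encodes an actin-binding protein, differed by 0.81 ± 0.17 (SE, 5 against 5 mice) in log2, while its other probe gave 0.02. Lmod1, a smooth muscle actin nucleator, differed by 1.39 ± 0.32, and Cebpd, a transcription factor of the acute phase and of fat cell differentiation, by 1.24 ± 0.29. Gpx3, the secreted glutathione peroxidase, differed by 1.04 ± 0.24 (SE), and by -0.12 in the log ratios of the scanner software. On the lower side stood N4bp3 (-0.48 ± 0.09), Ankrd37 (-0.54 ± 0.11), a gene induced by low oxygen, and Med20 (-0.31 ± 0.07), a subunit of the Mediator complex. Plec, the cytoskeletal linker plectin, differed by -0.42 ± 0.11 (-0.14 on the smallest of 3 probes), and Mterf1b was at least 1.15-fold lower, since it was well above background on 0 of 5 nano-TiO2 arrays. The smallest adjusted p was 0.274, for N4bp3, which was lower in all 5 treated mice than in any control. Leaving out nano-TiO2 day 1 replicate 1 gave 21 genes past the threshold. Leaving out the 3 arrays with almost no atrial transcripts, chosen after the data were seen, gave 44. With slide as a block 0 genes passed (1523 at unadjusted p under 0.05), as with scan day as a block (1657).

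Complement genes, the theme of the study, were on average higher in the day 1 nano-TiO2 hearts. The list of 24 measured members (of 33 listed) rose by a mean of 0.54 in log2 (camera adjusted p = 6.1e-05 over 27 lists; adjusted p = 0.441 with an estimated correlation), with 17 members higher and 7 lower. No member passed over all genes, 4 passed adjusted over the list alone, and 14 had an unadjusted p under 0.05. The study chose this theme on these same mice, so neither count is independent evidence. Cfd (complement factor D, also called adipsin, a product of fat cells) differed by 4.37 ± 1.29 (SE), or 20.7-fold, with 4 of 5 treated mice above every control. Without Cfd, which the adipocyte list also holds, the mean of the complement list was 0.38. C3, the central component of the cascade, differed by 1.31 ± 0.43 (0.16 on its other probe), C2 of the classical pathway by 1.26 ± 0.41, and clusterin (Clu), an inhibitor of the terminal complex, by 0.71 ± 0.17. Serping1, the C1 inhibitor, differed by 0.40 ± 0.15 and C1qb, a chain of the recognition molecule C1q, by 0.39 ± 0.15. Serping1 was -0.17 with plain background subtraction. The list mean per mouse was -0.56 ± 0.09 (SD, n = 5) in controls and -0.01 ± 0.38 (SD, n = 5) with nano-TiO2, relative to all mice (exact permutation p = 0.0317, two-sided, adjusted 0.141). The adipocyte and atrial marker means of the same mice differed by 1.92 and 1.24. Within the 4 slides that hold both groups the complement difference was 0.02, 0.39, 0.82 and 0.96, and within the 3 scan days 0.53, 0.42 and 0.67. With slide as a block it was 0.57.

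Among the other 26 fixed lists, 8 rose and 1 fell at day 1 by camera, and 0 of these calls held with an estimated correlation. Adipocyte markers rose by a mean of 1.92 in log2 (adjusted p = 1.2e-04; adjusted p = 0.441 with an estimated correlation). Of their 10 measured members 9 were higher, 0 passed over all genes and 6 adjusted over the list alone. Adipoq, which encodes the fat cell hormone adiponectin, differed 8.59-fold and Cidec, a protein of fat droplets, 8.48-fold (SE 1.06 and 1.08 in log2), each well above background on 1 of 5 control and 4 of 5 treated arrays. Atrial markers rose by 1.24 (adjusted p = 0.00510; adjusted p = 0.441 with an estimated correlation), with 6 of 6 members higher and 2 passing adjusted over the list alone. The difference was 2.05 without nano-TiO2 day 1 replicate 1 and 0.76 without control day 1 replicate 2, and ran from -2.38 to 3.93 within the 4 shared slides. Bmp10, a growth factor of the right atrium, was at least 2.78-fold higher, as it was well above background on 0 of 5 control arrays, and Stard10 differed by 1.57 ± 0.49. Nppa, the atrial natriuretic peptide, differed by 0.17 ± 0.13 (0.68 on its other probe). Mesothelium markers rose by 0.60 (adjusted p = 6.1e-05; adjusted p = 0.441 with an estimated correlation), with 8 of 8 members higher and 5 passing adjusted over the list alone. Among them Lrrn4 differed by 0.86 ± 0.26, Upk3b by 0.86 ± 0.31 and Upk1b by 0.77 ± 0.23.

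Glucocorticoid response genes rose by 0.54 at day 1 (adjusted p = 6.1e-05; adjusted p = 0.441 with an estimated correlation), with 14 of 14 members higher, 0 passing over all genes and 3 adjusted over the list alone. Sgk1, a salt-regulating kinase, differed by 0.95 ± 0.28 (SE) and Errfi1, an inhibitor of the EGF receptor, by 0.78 ± 0.26. Immediate early genes rose by 0.26 (adjusted p = 0.00510; adjusted p = 0.441 with an estimated correlation), with 16 of 21 higher and 3 passing adjusted over the list alone. Of these, Nr4a1, an orphan nuclear receptor, differed by 1.60 ± 0.46, Egr1 by 0.88 ± 0.24 and the phosphatase gene Dusp1 by 0.78 ± 0.25. Macrophage markers rose by 0.30 (adjusted p = 9.9e-04; adjusted p = 0.441 with an estimated correlation), with 12 of 14 higher, such as Lyve1 (0.76 ± 0.26, and 0.26 on its other probe), Mrc1, the mannose receptor (0.50 ± 0.21), and the Fc receptor Fcgr3 (0.33 ± 0.11, and 0.0891 on its other probe). Coagulation and vascular adhesion genes rose by 0.26 (adjusted p = 1.2e-04; adjusted p = 0.441 with an estimated correlation), with 17 of 18 higher. Examples were the thrombin receptor F2r (0.61 ± 0.19), F13a1 (0.55 ± 0.23) and the protein C receptor Procr (0.29 ± 0.12). Fibroblast markers rose by 0.28 (adjusted p = 0.00343; adjusted p = 0.535 with an estimated correlation), with 10 of 11 higher, among them Mfap5 (0.43 ± 0.22), Tcf21 (0.35 ± 0.17) and Dpep1 (0.29 ± 0.12). Their mean was 0.43 without nano-TiO2 day 1 replicate 1 and 0.16 without its replicate 4. In the macrophage, coagulation and fibroblast lists 0 members passed adjusted over the list alone. The adipocyte and atrial marker means of these mice differed by 1.92 and 1.24. With the mean of each group subtracted, the glucocorticoid and immediate early means of the 22 mice correlated with the adipocyte mean at r = -0.00701 and -0.102. The macrophage, coagulation and fibroblast means did so at 0.739, 0.721 and 0.782. Differences between the groups do not enter these values. The glucocorticoid mean per mouse was -0.40 in day 1 controls and 0.14 with nano-TiO2, against 0.15 and 0.07 in the same groups at day 28. The immediate early mean was -0.20 and 0.06, against 0.08 and 0.04. In both lists the day 1 controls thus lay apart, while the day 1 treated hearts lay near both day 28 groups. Within the 4 shared slides the glucocorticoid difference ran from -0.21 to 1.07, higher in 3. Cell cycle genes fell by 0.10 (adjusted p = 0.00646; adjusted p = 0.581 with an estimated correlation), with 17 of 19 lower and 0 passing adjusted over the list alone, but their mean was 0.10 with plain background subtraction and 0.17 with median centring, where the median of all genes was 0.17 too. Leaving out control day 1 replicates 1, 3, 4 or 5 in turn gave cell cycle means of -0.16, -0.17, -0.0421 and -0.0235. Ccnb2 (cyclin B2) differed by -0.20 ± 0.15 and Rrm2 by -0.20 ± 0.16. Nusap1 was well above background on 0 of 5 control and 2 of 5 treated arrays, so no size is given. Under median centring, where the median of all genes at day 1 was 0.17 (0.0141 without it), Ccnb2 was 0.11 and Rrm2 0.05, both below that median.

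The remaining 17 lists did not pass at day 1. Acute phase genes had a mean of 0.24 (0.0750 without nano-TiO2 day 1 replicate 2 and 0.37 without its replicate 1), with Cp (ceruloplasmin) at 0.28 ± 0.12 (SE), Hp (haptoglobin) at 2.04 ± 0.85 (-0.17 with adipocyte and atrial scores as covariates) and Itih4 at 0.17 ± 0.13. Cytokines and chemokines had a mean of 0.24, with 15 of 21 higher and 4 passing adjusted over the list alone. Ccl19, which draws T cells and dendritic cells, differed by 1.93 ± 0.55, Ccl9 by 0.52 ± 0.16 and Cxcl12, a stromal chemokine, by -0.50 ± 0.15 (-0.0693 on its other probe). The other means were 0.40 for neutrophil, 0.23 for erythroid, 0.14 for thymus, 0.11 for endothelial, 0.10 for skeletal muscle, 0.08 for B cell, -0.02 for T cell and -0.03 for lung epithelium markers. Those of the other processes were 0.19 for extracellular matrix and fibrosis, 0.08 for the interferon response, 0.07 for oxidative stress and metal response, 0.07 for heat shock, -0.01 for fatty acid oxidation, -0.05 for cardiac stress and contractile genes and -0.06 for the circadian clock. The B cell, T cell, lung epithelium and extracellular matrix differences were smaller in size than the SD among mice in either group. The mean, median and test differed in sign for 3 of the 27 lists at day 1, 1 of them heat shock, with a mean of 0.07 and a median of -0.04. Of the lists drawn up after the data were seen, smooth muscle markers, which hold Lmod1 named above, differed by 0.86. Liver markers differed by 0.08, and leaving out 1 mouse gave values from -0.29 (nano-TiO2 day 1 replicate 2) to 0.37 (its replicate 1).

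**Figure D1:**
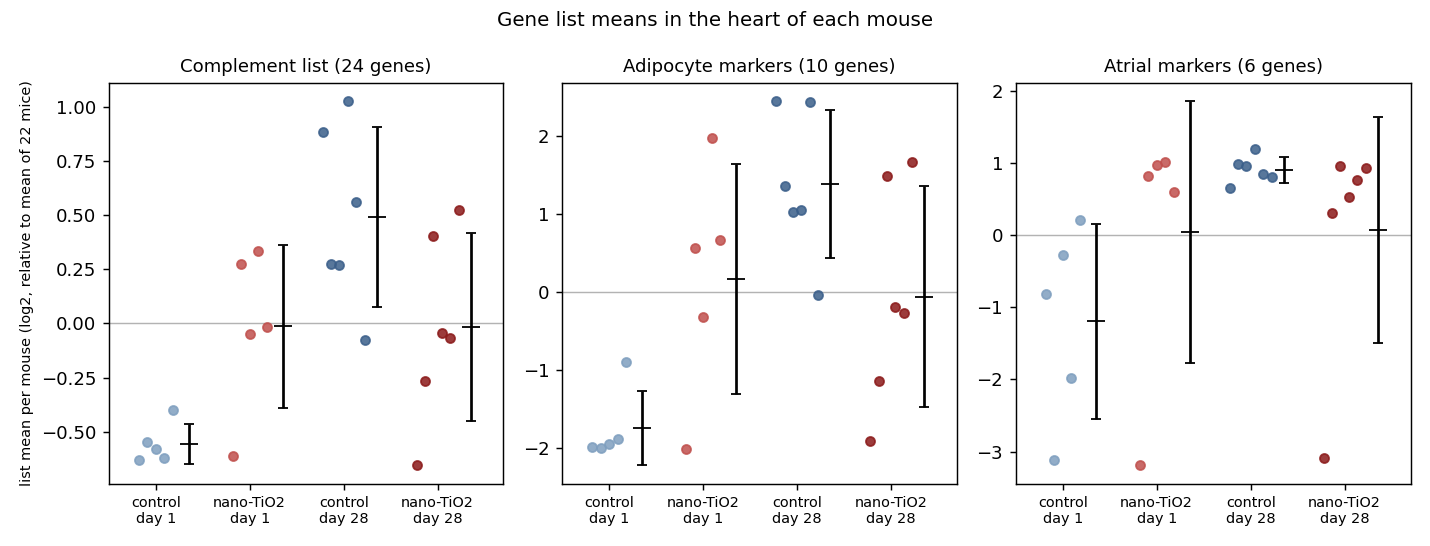
Mean of the complement, adipocyte and atrial lists in each mouse (points; log2, relative to the mean of all 22 mice) by group, with the group mean and SD beside the points. The complement mean was -0.56 ± 0.09 in day 1 controls and 0.49 ± 0.42 in day 28 controls, and 3 hearts had an atrial mean below -3.

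The second comparison asked which heart genes differed from control 28 days after instillation. limma called 0 of 15502 genes, with 1179 at an unadjusted p under 0.05, of which 347 were higher and 832 lower, and the smallest adjusted p was 0.636. Slc27a2, a fatty acid transporter of liver and kidney, differed by -1.04 ± 0.23 (SE, 6 against 6 mice) and was well above background on 5 control arrays and 1 treated array. Inmt, an indole methyltransferase of lung, differed by -0.65 ± 0.15, Olfml2b by -0.52 ± 0.12 and Enpp5 by -0.33 ± 0.08. On the higher side Plin3, a coat protein of lipid droplets, differed by 0.50 ± 0.15, and Suclg2, a subunit of the succinate-CoA ligase of mitochondria, by 0.36 ± 0.10 (0.12 on its other probe). Arhgef10l differed by 0.31 ± 0.09, R3hdm1 by 0.26 ± 0.07, and the olfactory receptor gene Olfr1309 by 0.30 ± 0.07, the last well above background on 1 control and 2 treated arrays. The lung epithelium and liver marker means of the same mice differed by -0.70 and -1.61. Leaving out control day 28 replicate 6 gave 3 genes past the threshold. With slide as a block 0 genes passed (1080 at unadjusted p under 0.05), as with scan day as a block (1453).

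The complement list fell by a mean of 0.51 in log2 at day 28 (camera adjusted p = 8.9e-08; adjusted p = 0.341 with an estimated correlation), with 22 of 24 members lower. No member passed over all genes, 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05; the list is the study's own theme on these mice, so this is not independent evidence. Hc (complement C5) was at least 1.89-fold lower and Mbl2 (mannose-binding lectin) at least 1.88-fold lower, both well above background on 0 of 6 treated arrays, and on 4 and 3 of 6 control arrays. Cfi (factor I), which cuts active C3, differed by -0.99 ± 0.38 (SE) and was well above background on 4 control and 2 treated arrays. C8g differed by -0.65 ± 0.22, Serping1 by -0.47 ± 0.14 and C1ra, a protease of the C1 complex, by -0.43 ± 0.16. The list mean per mouse was 0.49 ± 0.42 (SD, n = 6) in controls and -0.02 ± 0.43 (SD, n = 6) with nano-TiO2 (exact permutation p = 0.0714, two-sided, adjusted 0.222). Adipocyte, liver and lung epithelium markers of the same mice differed by -1.44, -1.61 and -0.70. Without the 5 arrays with lung epithelium or liver transcripts, chosen after the data were seen, the complement difference was -0.12 (adjusted p = 0.644), in 2 controls against 6 treated mice, since 4 of these arrays were day 28 controls. Without the 3 arrays with most of them, all day 28 controls, it was -0.17 (adjusted p = 0.134). Both changes may be in part built in, since the arrays were picked by markers that move with complement. With group means subtracted, the complement and liver means correlated at r = 0.72. Within the 6 slides the complement difference was lower in 4 and higher in 2, from -1.54 to 0.60, and within the 3 scan days -0.47, -1.04 and -0.01. With slide as a block it was -0.51, as it must be with 1 array of each group on every slide.

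Among the other 26 lists, 7 fell and 2 rose at day 28 by camera, and 0 held with an estimated correlation. No member passed over all genes, and in the adipocyte list 2 passed adjusted over the list alone, against 0 in the other 8. Adipocyte markers fell by 1.44 in log2 (adjusted p = 1.1e-04; adjusted p = 0.341 with an estimated correlation), with 9 of 10 lower. Ucp1, the uncoupling protein of brown fat, differed by -3.49 ± 0.84 (SE), well above background on 6 of 6 control and 4 of 6 treated arrays. Plin1, which coats fat droplets, differed by -2.04 ± 0.83 and Cidea by -0.42 ± 0.13, while Cidea was 0.05 with plain background subtraction and 0.08 in the scanner log ratios. Acute phase genes fell by 0.72 (adjusted p = 1.1e-04; adjusted p = 0.341 with an estimated correlation), with 12 of 12 lower. The fibrinogen chains Fgg (-2.05 ± 0.79) and Fgb (-1.93 ± 0.75) were well above background on 4 control and 2 treated arrays, and haptoglobin (Hp) differed by -1.88 ± 0.78. Liver markers differed by -1.61, and without the 5 arrays with lung epithelium or liver transcripts Fgg was 0.34 and Fgb 0.43, with 2 controls left. Fgb is in the liver list by which arrays were picked, so its change is in part built in. Mesothelium markers fell by 0.54 (adjusted p = 7.1e-06; adjusted p = 0.341 with an estimated correlation), with 8 of 8 lower, as Lrrn4 (-0.61 ± 0.23) and the keratins Krt8 (-0.63 ± 0.25) and Krt18 (-0.63 ± 0.26). Fibroblast markers fell by 0.31 (adjusted p = 1.9e-04; adjusted p = 0.360 with an estimated correlation), with 11 of 11 lower, among them Dpt (-0.47 ± 0.18), Gsn (-0.44 ± 0.22) and Pi16 (-0.43 ± 0.21).

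Macrophage markers fell by 0.23 at day 28 (adjusted p = 3.1e-04; adjusted p = 0.360 with an estimated correlation), with 14 of 14 lower. Cathepsin S (Ctss) differed by -0.45 ± 0.22 (SE), Fcgr3 by -0.21 ± 0.10 and Clec4n by -0.18 ± 0.09, Clec4n being well above background on 5 control and 2 treated arrays. Cytokines and chemokines fell by 0.21 (adjusted p = 0.0206; adjusted p = 0.360 with an estimated correlation), with 18 of 21 lower. Il33, an alarm cytokine, differed by -0.56 ± 0.22, Ccl9 by -0.32 ± 0.14 and Cxcl12 by 0.30 ± 0.14 (0.0878 on its other probe). Coagulation and vascular adhesion genes fell by 0.15 (adjusted p = 0.0161; adjusted p = 0.405 with an estimated correlation), with 14 of 18 lower, among them Fgl2 (-0.47 ± 0.21), the adhesion molecule Vcam1 (-0.38 ± 0.18, and -0.00130 on its other probe) and Procr (-0.24 ± 0.11). Under 8 alternatives of background correction and scaling, the coagulation list passed in 5 and the cytokine list in 6. Cardiac stress and contractile genes rose by 0.17 (adjusted p = 4.0e-06; adjusted p = 0.341 with an estimated correlation), with 23 of 25 higher. Examples were phospholamban (Pln, 0.32 ± 0.13), which restrains the calcium pump, connexin 43 (Gja1, 0.27 ± 0.12) and Tpm1 (0.32 ± 0.16), whose other probe gave -0.26. Fatty acid oxidation genes rose by 0.14 (adjusted p = 1.4e-04; adjusted p = 0.341 with an estimated correlation), with 21 of 24 higher, among them Hadha (0.34 ± 0.12), Mlycd (0.31 ± 0.14) and Eci1 (0.26 ± 0.12). Under the same 8 alternatives their mean ran from 0.00490 to 0.19, passing in 7, and that of the cardiac list from 0.03 to 0.23, passing in 8. Without nano-TiO2 day 28 replicate 1 the difference was -0.14 for macrophage, -0.10 for coagulation and -0.20 for fibroblast genes. Adipocyte markers of the same mice differed by -1.44. With group means subtracted, the cardiac list correlated with the adipocyte mean at r = -0.70 and with the complement mean at -0.72. Fatty acid oxidation genes correlated with the adipocyte mean at -0.31. Macrophage, cytokine, coagulation, fibroblast, mesothelium and acute phase means did so at 0.74, 0.81, 0.72, 0.78, 0.92 and 0.47. Differences between the groups do not enter these values. The cardiac rise was thus not shown to be separate from the adipocyte and complement falls. The remaining 17 lists did not pass. Their means were -0.84 for atrial markers (-0.21 without nano-TiO2 day 28 replicate 1) and -0.70 for lung epithelium (-0.37 without control day 28 replicate 1 and -0.39 without its replicate 5). They were -0.29 for thymus, -0.24 for B cell, -0.13 for T cell, -0.13 for erythroid, -0.02 for neutrophil, 0.02 for endothelial and 0.08 for skeletal muscle markers. Extracellular matrix and fibrosis had -0.13, glucocorticoid response -0.09, interferon response -0.08, heat shock -0.06, circadian clock -0.05, oxidative stress and metal response -0.05, immediate early genes -0.04 and cell cycle 0.06. Smooth muscle and liver markers, listed after the data were seen, differed by -0.57 and -1.61.

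**Figure D2:**
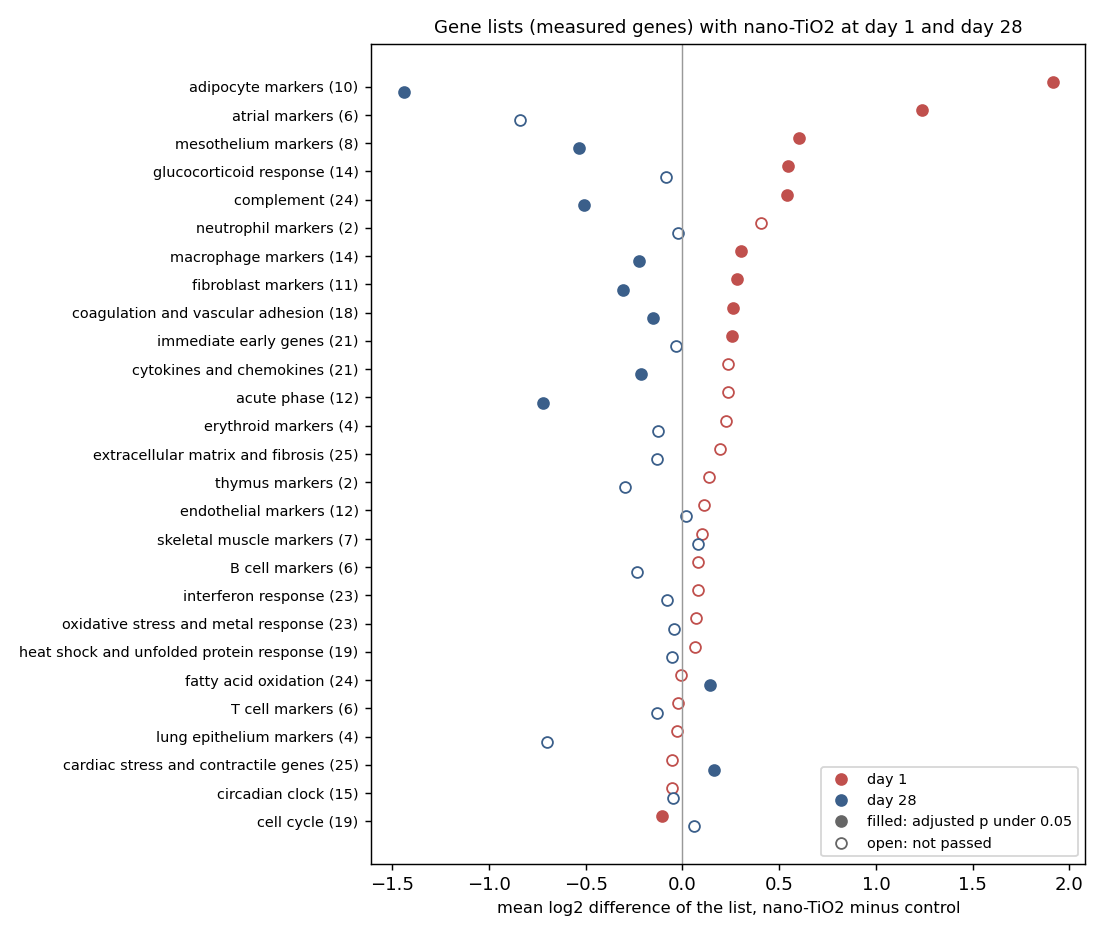
Mean log2 difference between nano-TiO2 and control mice of each of the 27 gene lists at day 1 (red) and day 28 (blue), filled where the camera adjusted p was under 0.05 and with the number of measured genes in brackets. Adipocyte markers were 1.92 higher at day 1 and differed by -1.44 at day 28, and complement genes by 0.54 and -0.51. The cell cycle mean at day 1 was 0.17 with median centring, as was the median of all genes.

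The third comparison tested whether the nano-TiO2 difference itself changed between day 1 and day 28. limma called 0 of 15502 genes, with 2289 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0692. Of the named genes with the smallest p on the lower side, Lmod1 had a day 28 difference that was lower than that of day 1 by -2.28 ± 0.43 in log2 (SE), and Myh11, the smooth muscle myosin, by -1.89 ± 0.37. Prdm6, a regulator of smooth muscle genes, was lower as well, but it was well above background on 0 of 5 day 1 control arrays, so no size is given. Fmo2, a monooxygenase of lung, differed by -1.43 ± 0.26 and Crip1 by -1.24 ± 0.24. On the higher side stood Suclg2 (0.66 ± 0.15, and 0.35 on its other probe), Hnrnpc (0.60 ± 0.14), R3hdm1 (0.53 ± 0.11), N4bp3 (0.53 ± 0.12) and Pphln1 (0.39 ± 0.10, and 0.00764 on its other probe). The complement list differed by -1.05 between the days (camera adjusted p = 3.8e-08; adjusted p = 0.316 with an estimated correlation), with 22 of 24 members lower and 11 passing adjusted over the list alone. Adipocyte markers differed by -3.35, atrial markers by -2.07 and mesothelium markers by -1.14 in the same direction. The means of these lists moved between the days mainly in the controls. Complement went from -0.56 to 0.49 in controls and from -0.01 to -0.02 with nano-TiO2. Adipocyte markers went from -1.75 to 1.38 in controls and from 0.17 to -0.06 with nano-TiO2. Atrial markers went from -1.20 to 0.90 and from 0.04 to 0.06. In all, 14 of 27 lists passed, 3 higher and 11 lower, 0 with an estimated correlation and 4 by fry one way. The signs of mean, median and test differed for 1 list, skeletal muscle markers, at -0.02, 0.01 and up. Leaving out single mice gave 312 genes without nano-TiO2 day 1 replicate 1, 180 without nano-TiO2 day 28 replicate 3, 99 without control day 28 replicate 6 and 33 without nano-TiO2 day 28 replicate 6. With scan day as a block 6 genes passed, all lower, and with slide as a block 0 (2264 at unadjusted p under 0.05).

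Across genes, the day 1 and day 28 differences were related inversely, with Pearson r = -0.54 and Spearman rho = -0.41 over 15502 genes, which are not independent replicates. Of 100 labellings of treatment within each day, the real one included, 8 gave a Pearson value as large in size and 14 a Spearman value. The relabelled Pearson values ran from -0.61 to 0.69.

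Control hearts of the 2 days were compared as the background to both treatment comparisons, and they differed in more genes than either. Between day 1 and day 28 controls 1091 genes rose and 536 fell (limma, 1627 of 15502), and 586 of these differed by at least 1.5-fold. Of alternatives chosen after the data were seen, leaving out the arrays with lung epithelium or liver transcripts left 1 gene (2 against 5 mice), leaving out the 3 with most left 32, and adipocyte and atrial scores as covariates left 0. Liver markers had a mean of -0.21 in day 1 and 0.95 in day 28 controls, and lung epithelium markers -0.16 and 0.49. Single day 28 controls ran from -0.99 to 3.20 in liver and from -0.45 to 2.13 in lung epithelium markers. Itga8, an integrin chain of smooth muscle and mesenchymal cells, rose by 3.08 ± 0.47 in log2 (SE, 6 against 5 mice; adjusted p = 0.00258). Tpm2, a tropomyosin, rose by 1.46 ± 0.22, Crip1 by 1.10 ± 0.17 and Tmem37 by 0.81 ± 0.12 (0.00758 on its other probe). The mesothelial gene Lrrn4 rose by 1.57 ± 0.24 (adjusted p = 0.00268), being well above background on 1 of 5 day 1 and 6 of 6 day 28 arrays. Plk2 fell by 0.67 ± 0.11 (SE), the methyltransferase gene Kmt5a by 0.63 ± 0.11, Tspan13 by 0.63 ± 0.09, cytochrome c1 (Cyc1) by 0.50 ± 0.09 and N4bp3 by 0.49 ± 0.09. The count rests on the background correction: where the correction was fitted on all spots, those with an uneven background included, 79 genes passed, all of them among the 1627. That choice was made after both results had been seen. With slide as a fixed block, where 3 slides hold both groups, 0 genes passed (2809 at unadjusted p under 0.05), and with slide as a random block 1646 did, at a correlation within slides of 0.0190. With scan day as a block 1926 passed. The share of higher genes was 67.1% here, 47.3% in the scanner log ratios, 48.2% in Cy5 alone, 92.4% with the correction fitted on all spots and 100% with median centring. Under median centring 87 genes passed, and the median of all genes was 0.13 here (-0.00242 without it) and -0.27 in the third comparison (-0.0203 without it). Leaving out 1 mouse gave 957 genes without control day 1 replicate 2, 960 without control day 28 replicate 4, and 1070 without control day 1 replicate 1 or control day 28 replicate 5.

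Complement genes rose by 1.05 from day 1 to day 28 controls (camera adjusted p = 1.3e-09; adjusted p = 0.203 with an estimated correlation), with 14 of 24 members past the threshold over all genes, all higher, and 16 adjusted over the list alone. Without Cfd the list rose by 0.83, and by 0.20 ± 0.18 (SE) with adipocyte and atrial scores as covariates, chosen after the data were seen. Cfd rose by 6.12, C3 by 2.37, C4b by 1.96 and Clu by 0.77. The difference was 1.43, 0.85 and 0.96 within the 3 shared slides, and 1.23, 1.17 and 0.75 within the scan days. Adipocyte markers rose by 3.12 (adjusted p = 1.5e-05; adjusted p = 0.212 with an estimated correlation), with 7 of 10 members rising and 1 falling. Atrial markers rose by 2.10 (adjusted p = 0.00244; adjusted p = 0.283 with an estimated correlation) and mesothelium markers by 1.24 (adjusted p = 3.5e-09; adjusted p = 0.203 with an estimated correlation), with 8 of 8 members past the threshold. The other lists that rose were acute phase (0.76), fibroblast (0.56), glucocorticoid response (0.55), macrophage (0.53), cytokines and chemokines (0.51), extracellular matrix and fibrosis (0.38), coagulation and vascular adhesion (0.34), interferon response (0.29; 0.13 without control day 28 replicate 4) and immediate early genes (0.28). Their adjusted p lay between 0.212 and 0.583 with an estimated correlation. Cardiac stress and contractile genes fell by 0.34 (adjusted p = 8.5e-09; adjusted p = 0.203 with an estimated correlation), with 7 of 25 members falling. With group means subtracted, the mean of this list correlated with the adipocyte mean at r = -0.70. Fatty acid oxidation genes fell by 0.21 (adjusted p = 2.4e-05; adjusted p = 0.212 with an estimated correlation), with 8 of 24 falling. Their mean was 0.02 with median centring, which lay below the median of all genes there (0.13). In all 15 of 27 lists passed, 0 with an estimated correlation and 13 by fry one way. For 2 lists, circadian clock and heat shock, the mean was 0.01 and 0.05 and the median -0.03 and -0.04.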

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

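The tests of slide at day 1, of scan day between control days, of failed arrays and shared slides for the 3 hearts, and the splits of the mice for the gene counts of the 3 treatment comparisons were chosen after the results were seen. A single mouse stood out when the gap between its value and the nearest other mouse was too large a share of the range of its group (Dixon test). Chance alone picks out about 1 in 20 groups, and here 9 of 108 groups of list means and 15 of 396 groups of gene values had one.

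Control day 1 replicate 5 lay above the other day 1 controls in adipocyte markers (list mean -0.90 in log2), Cfd (5.04), Adipoq (1.98) and Cidec (2.01), and below them in C8g (0.0251). Nano-TiO2 day 1 replicate 1 lay below its group in atrial markers (-3.19), Gpx3 (3.21), Cfd (0.93), Krt18 (-5.47) and Itga8 (1.09). Nano-TiO2 day 28 replicate 1 lay below its group in atrial markers (-3.09) and Serping1 (2.73) and above it in Sgk1 (0.35). Control day 1 replicate 4 lay above its group in fatty acid oxidation (0.27) and glucocorticoid response genes (-0.0279). Nano-TiO2 day 1 replicate 4 was high in B cell markers (0.32) and low in Sgk1 (-1.12), and nano-TiO2 day 1 replicate 2 was high in neutrophil markers (0.36) and Mbl2 (1.35). Control day 28 replicate 3 was low in T cell markers (-0.16) and high in Cyc1 (2.07). Nano-TiO2 day 28 replicate 3 was high in heat shock genes (0.18), nano-TiO2 day 28 replicate 5 low in Errfi1 (-1.61), and control day 1 replicate 3 low in Actc1 (5.50).

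For 14 lists the nano-TiO2 difference at day 28 differed from that at day 1 by the test of that difference (camera), and 0 of these calls held with an estimated correlation. Complement genes differed by -1.05, adipocyte markers by -3.35, atrial markers by -2.07, mesothelium markers by -1.14 and acute phase genes by -0.96. In the complement, adipocyte and atrial lists the treated hearts hardly moved between the days, while the controls rose by 1.05, 3.12 and 2.10. Glucocorticoid response genes differed by -0.63, fibroblast markers by -0.59, macrophage markers by -0.53, cytokines and chemokines by -0.45, coagulation and vascular adhesion genes by -0.41 and immediate early genes by -0.29. Cardiac stress and contractile genes differed by 0.22, cell cycle genes by 0.16 and fatty acid oxidation genes by 0.15, and under median centring all 3 were negative (-0.22, -0.25 and -0.24) but above the median of all genes there (-0.27). Cell cycle genes were -0.10 with plain background subtraction and -0.0199 in the scanner log ratio and passed in 3 of 8 scalings, and fatty acid oxidation genes were -0.0631 with normexp fitted on all spots. Cell cycle genes were 0.10, 0.0858 and 0.11 without control day 1 replicate 4, its replicate 5 or control day 28 replicate 3, and fatty acid oxidation genes 0.0961 without nano-TiO2 day 1 replicate 4.

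The complement list was higher with nano-TiO2 at day 1 and lower at day 28. Slide is argued against at day 1, as the mean difference within the 4 shared slides was 0.54 and all 4 were higher. With adipocyte and atrial scores as covariates the list without Cfd went from 0.38 ± 0.20 (SE) to 0.00776 ± 0.15 at day 1, and from -0.45 ± 0.18 to -0.14 ± 0.14 at day 28, while the adipocyte score alone gave 0.00799 and -0.14 and the atrial score alone 0.24 and -0.35. In these fits the shifts shrank while the SE did not grow, though at day 1 the shift lay under 2 SE even without covariates. Fat in the pieces may account for both shifts unless the scores themselves respond to treatment. At day 28 material with liver or lung epithelium markers may equally do so. Leaving out the 5 arrays highest in those markers gave -0.12 for the whole list with 2 controls left. That change may be in part built in, since the complement and liver means correlated at r = 0.72 with group means subtracted. The surfactant genes Sftpc and Sftpb were well above background on 0 of 22 arrays, so lung tissue itself was not shown. Chance cannot be excluded, since 6 of 100 splits of the mice gave a p as small at day 1 (real 6.8e-06, smallest other 1.5e-07) and 7 of 100 at day 28 (3.3e-09 and 1.3e-11), and a response of complement genes to nano-TiO2 stays open.

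Between the control days 1627 genes differed. Chance is argued against, as 1 of 100 splits, the real one, gave as many (highest other 400, with 462 splits possible). The splits used the background fit chosen after its count had been seen, and were not run with slide as a block. Scan day is argued against, since 1926 genes passed with scan day as a block, 1603 of them among the 1627. With adipocyte and atrial scores as covariates the median absolute log2 difference of the 1627 genes went from 0.48 to 0.17 and 0 passed (796 at unadjusted p under 0.05), while the median SE rose from 0.12 to 0.15. Fat and atrial content may account for most of it, with 1474 of 1627 genes keeping their direction. Material with liver or lung epithelium markers stays open as well. Without the 5 arrays highest in those markers 1 gene passed (2 against 5 mice), and 32 without the 3 highest. These counts cannot decide it, since fewer mice lower them whatever the cause, and leaving out 1 mouse already gave as few as 957. Adipocyte means reached at most -0.90 in day 1 controls and at least -0.04 in day 28 controls, and atrial means 0.21 and 0.65. With no overlap between the control groups, the covariates cannot tell tissue content from another cause that differs between these groups. The 28 days between the groups, the age of the mice and the time since anaesthesia stay open as untested, and slide in part, with 0 genes passing when it was a fixed block and 1646 when it was a random one.

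In 3 hearts (control day 1 replicate 2, nano-TiO2 day 1 replicate 1 and nano-TiO2 day 28 replicate 1) the atrial markers were almost absent, with a median difference from the other 19 hearts of -3.71 in log2. Failed arrays are argued against, since at least 15197 probes were well above background on each, within the 13473 to 21751 of the others. An effect on whole slides or a whole scan day is argued against, as the 3 other arrays of the same slides had atrial means of -0.81, 0.81 and 0.65. These lie within the -1.98 to 1.19 of the arrays on other slides. The low end of that range is control day 1 replicate 4, itself low, and the next value there is -0.28, above the -0.81 of 1 slide mate. All 3 hearts were scanned on 1 day (3 of its 8 arrays, 0 of the other 14) and 2 shared a slide, so handling that day stays open. Atria missing from the piece used for RNA may be the source, but a further list of 4 atrial genes had a median of -0.52 and ventricular genes one of 0.34, which does not decide it. Sln (-6.91), Myl4 (-5.38) and Myl7 (-5.26) were far lower in these hearts, and Nppa (-0.06) was not.

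For the gene counts of the 3 treatment comparisons the splits decide nothing about chance, because the real count was 0 and every split must give at least as many. All 100 did so at day 1 (highest other 60), all 100 at day 28 (highest other 48) and all 100 for the difference between the days (highest other 403). Any gene passed in 2 splits at day 1 and in 4 at day 28. A split with many genes points to a structure of the samples, which was not tested further. The split with 60 genes set nano-TiO2 day 1 replicate 1 with 4 day 1 controls, and that side minus the other was -2.60 in atrial and -2.37 in adipocyte markers.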

How the results depend on the processing

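The normexp fit on all spots, the runs without arrays chosen by atrial, lung epithelium or liver markers, the covariates, the complement list without Cfd and the exact permutation were chosen after the data were seen. Where a result changed below, the cause was not tested unless stated.

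The complement difference kept its direction under all 27 alternatives at each day, from 0.07 to 0.70 at day 1 (adjusted p from 2.7e-07 to 0.725) and from -0.72 to -0.11 at day 28 (adjusted p from 2.0e-10 to 0.644). Several of the 27 could not change it. The other set tests, exact permutation, trend and robust eBayes and only the compared groups use the same difference. At day 28 the slide and scan day blocks leave it unchanged too. The list lost its call under 4 and 7 of the 27, or under 5 at day 1 if the exact permutation there is read by its p adjusted over the lists (0.141) and not by its own (0.0317). At day 1, where it was 0.54, the adjusted p was 0.441 for camera with an estimated correlation, 0.237 for fry one way and 0.221 for fry mixed, and with adipocyte and atrial scores as covariates the difference was 0.0692 (adjusted p = 0.725). At day 28, where it was -0.51, the adjusted p was 0.341 and 0.246 in the first 2 of these tests, fry mixed did not pass either, and the exact permutation p was 0.0714. There it was -0.12 (adjusted p = 0.644) without the 5 arrays with lung epithelium or liver transcripts, which leaves 2 controls, -0.17 (0.134) without the 3 with most, which leaves 3, and -0.11 (0.461) with the covariates.

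Counts of genes moved as follows. The scanner log ratio gave 7 at day 1, 45 for the difference between days and 3864 between control days, and array weights 4, 106 and 2694. Between control days, median centring gave 87, the normexp fit on all spots 79, slide as a fixed block 0 (1646 as a random block), a fold of at least 1.5 as well 586, the covariates 0, and leaving out the arrays with lung epithelium or liver transcripts 1, or 32 without those with most. On the fit with all spots the 3 arrays with extreme background values had a far wider fitted background, and the median SD over genes was 0.203 against 0.170. Scan day as a block gave 6 for the difference between days. An unadjusted p under 0.05 gave 1339, 1179, 2289 and 3933 in the 4 comparisons. Without the 3 arrays with almost no atrial transcripts 44 genes passed at day 1 and 95 for the difference between days.

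Counts of the other lists were 0 in all 4 comparisons with an estimated correlation, 0 at day 1 and day 28 by fry in either form, and 3 (one way) and 1 (mixed) for the difference between days. At day 28 they were 4 without the arrays with lung epithelium or liver transcripts and 3 with the covariates, which gave 6 for the difference between days and 6 between control days. The correlation of the day 1 and day 28 differences was -0.45 with no filter on dim probes, where 4 of 100 labellings gave one as large (p from 0.04 to 0.16 over its alternatives), -0.42 without the arrays with lung epithelium or liver transcripts and -0.12 with the covariates.

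Leaving out each of the 22 arrays gave 0 to 21 genes at day 1, 0 to 3 at day 28, 0 to 312 for the difference between days and 957 to 2070 between control days. Of the arrays that moved a count more than 1.5-fold, nano-TiO2 day 1 replicate 1 gave the 21 and the 312 and control day 28 replicate 6 the 3. For the difference between days 99 genes passed without control day 28 replicate 6, 180 without nano-TiO2 day 28 replicate 3 and 33 without its replicate 6. Between control days 957 passed without control day 1 replicate 2, 1070 without its replicate 1, 960 without control day 28 replicate 4 and 1070 without its replicate 5. The complement difference ran from 0.45 to 0.70 at day 1 and from -0.62 to -0.38 at day 28, with the call in all 22. Other lists passing ran from 7 to 12, 8 to 12, 11 to 14 and 14 to 15.

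Of the named genes 15 values had the other sign, none past the threshold in either. With plain background subtraction the values were -0.17 (Serping1, day 1), 0.19 (Nusap1, day 1) and 0.0538 (Cidea, day 28). With the Agilent log ratio they were -0.12 (Gpx3, day 1), 0.00802 (Nusap1, day 1) and 0.0759 (Cidea, day 28). With median centring and no loess they were 0.00439 (Nusap1, day 1), 0.11 (Ccnb2, day 1) and 0.0517 (Rrm2, day 1), and in Cy5 alone 0.0165 (Nusap1, day 1). Without the arrays with lung epithelium or liver transcripts they were 0.14 (Mbl2, day 28), 0.34 (Fgg, day 28) and 0.43 (Fgb, day 28), and with the covariates -0.17 (Hp, day 1) and 0.0496 (Plin1, day 28), the latter by construction, since Plin1 is part of the adipocyte score. The change of Fgb is in part built in, since Fgb is in the liver list by which arrays were picked. No alternative with mean intensities was run, because the files hold medians only. Signal over background limits genes such as Mbl2 and Hc, which were not well above background on any treated array at day 28.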

Other observations

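The lists described here were drawn up after the data were seen, except lung epithelium and B cell markers. Smooth muscle markers (11 measured genes, such as Myh11 and Lmod1) had a mean per mouse of -0.74 ± 0.17 (SD, n = 5) in day 1 controls and 0.13 ± 0.47 (SD, n = 5) with nano-TiO2, and of 0.54 ± 0.22 (SD, n = 6) in day 28 controls and -0.03 ± 0.54 (SD, n = 6) with nano-TiO2. Between the control days they differed by 1.28, for which no p is given, since the list holds genes that had already stood out. The further atrial list of 4 genes differed by 0.36 at day 1, -0.34 at day 28 and 0.76 between the control days (exact permutation p = 0.119, 0.0823 and 0.00216, the last the smallest that these group sizes allow). The 8 ventricular markers differed by -0.08, 0.14 and -0.40 (exact permutation p = 0.429, 0.134 and 0.00433).

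Some day 28 control hearts had high values of liver or lung epithelium markers, whose origin was not tested. Liver markers (9 measured genes, such as albumin) lay 3.20 above the mean of all mice in control day 28 replicate 4 and 2.75 above it in replicate 1. They lay 1.02 above it in control day 28 replicate 3 and 1.36 above it in nano-TiO2 day 1 replicate 2. Lung epithelium markers lay 2.13 above it in control day 28 replicate 1 and 2.04 in its replicate 5. B cell markers lay 1.38 and 1.20 above it in the same hearts. B cell markers also lay 1.17 above it in nano-TiO2 day 28 replicate 6, where lung epithelium markers were at 0.0074. The surfactant genes Sftpc and Sftpb were well above background on 0 of 22 arrays, these included. The fibrinogen gene Fgb is in both the liver and the acute phase list.

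For the other named genes with more than 1 probe, the probe furthest from the value given in the report had the same direction. At day 1 it gave -0.27 for Med20, 0.70 for C2 and 1.66 for Ccl19. At day 28 it gave -0.37 for Fgl2, -0.16 for Fcgr3 and -0.46 for Krt8, and between control days 2.37 for Itga8, 1.19 for Tpm2 and -0.35 for Kmt5a.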
